A study of Mus musculus with 2 samples.

How the data were processed

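The series profiled whole dissociated kidney of wild-type C57BL/6 mice by droplet single-cell RNA sequencing. Per the labels' protocols, mice aged 8 weeks received 1 intraperitoneal dose of an antibody against CSF1R or of an isotype control antibody, and kidneys were taken on day 7 from 2 mice per group. The tissue was digested with liberase at 0.2 mg/ml and 37 °C for 25 minutes and passed through 70 µm and 40 µm strainers. The labels describe no sort or enrichment of a cell type. Libraries were made with the 10x Genomics Chromium Next GEM Single Cell 3′ kit, version 3.1, per the labels' protocols. The block structure of the barcodes raises an untested doubt about that version, given among the other observations. Cell Ranger 3.1.0 is named in the submitters' processing notes. The genome build and gene annotation used for counting are not given in the sources used here.

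The files analysed were, for each of the 2 libraries, the list of cell barcodes and the list of genes that label the columns and rows of a filtered gene-by-cell matrix as Cell Ranger writes it. The submitters' names for these files call the barcode set filtered, which in Cell Ranger output means barcodes called as cells. Both kinds of file hold text and no measurement. Counts per gene and cell were not used here. For that reason no expression level, cell class, share of cells, depth per cell or quality filter on cells was computed, and no doublet caller was run. The cell classes, the rule for naming changed genes and the summed expression per class that had been fixed before the data were examined could not be applied. The marker and gene lists fixed at the same time were used to ask whether the annotation behind the matrix holds each gene. They were also used to ask which of these genes overlap another listed gene on the same strand. The design has 1 library per group, so no test between the groups was possible, and no p-value is given.

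Barcodes were counted per library with an exact Poisson interval at the 95% level. The ratio of the 2 counts was given an exact interval conditional on their sum. These intervals cover counting error only, not variation between mice, digestions or chip lanes. Barcodes were compared between libraries after removal of the suffix that Cell Ranger adds, and pairs at 1 mismatch were sought within and between libraries. The size of the barcode pool that independent draws would need was the product of the 2 library sizes divided by the number of shared barcodes. A separate pool size was built from the barcodes' own block structure, by joining each first block to each last block with the same middle pair of bases. Both calculations were tested on simulated data of the same library sizes. In 100 simulated pairs of libraries, the interval held the true pool size in 94 and the block count came within 1% of it in 100. An excess was found in 100 of 100 simulated pairs to which 100 copied barcodes had been added. That is more copies than the 92 barcodes shared in the data, so it does not show that a smaller excess would be found. Smaller excesses were not simulated. The same 100 pairs held no copies before these were added, and 94 is the number whose interval held the true pool size at that stage. How many of the rest showed an excess rather than a shortfall was not counted. The simulated pool also differed in size from the pool of the data. The simulated libraries drew evenly from every joining of first and last blocks with the same middle pair, which is what the block count assumes. The simulation therefore checks the calculation, and cannot show that the real pool holds every such joining or was drawn evenly.

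Gene identifiers were matched without version numbers to GENCODE release M21 of the mouse annotation, and 32235 of 32285 (99.8%) were found. Of the matched identifiers, 31502 carried the same symbol in M21 and 733 carried another. M21 was used for gene classes and for which genes overlap on the same strand. Its coordinates are not printed, because the build behind the files is not named. The overlap check was chosen after the gene lists had been read. Calculations used Python 3.11.15 and SciPy 1.17.1.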

Results

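The experiment asked how the mouse kidney changes when its resident macrophages are depleted with an antibody against CSF1R, the receptor for the growth factors CSF1 and IL-34 on which many tissue macrophages depend. It comprised 2 single-cell libraries, 1 of kidney from the group given the anti-CSF1R antibody and 1 of kidney from the group given an isotype control antibody, both taken on day 7 after a single injection. The labels give 2 mice per group and 1 library per group, and each library's barcodes carry a single suffix with no mark of the animal. The labels do not state outright that cells of both mice were pooled, so whether a library holds 1 animal or 2 is unknown. They also give 8 mice in all, more than these groups account for, and the use of the other mice is not stated in the labels analysed here. The animals could therefore not be treated as replicates. Only the lists of barcodes and genes were analysed here. The level of any gene, the share of macrophages and the depth of each cell were not measured, so the extent of depletion and the response of other kidney cells are not reported.

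The control library listed 16985 cell barcodes (exact 95% Poisson interval 16731 to 17242), and the anti-CSF1R library listed 17661 (17402 to 17923). The anti-CSF1R library held 676 more barcodes, a ratio of 1.04 (exact 95% interval 1.02 to 1.06), or 3.98% more. The interval covers counting error alone. The number of cells loaded for each library is not given in the labels, and there is no second library of either group against which to set the difference. It is a difference in barcodes called as cells, over all cell types together, and not a measured difference in the number of cells in the kidney. Each barcode had 16 bases and occurred once in its library.

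The annotation behind both libraries was the same: the lists matched in content and order and held 32285 gene identifiers, all of 1 feature type. By GENCODE M21 class, 21702 were protein-coding genes, which is 98.5% of those in M21. A further 5605 were lincRNA genes and 2955 were antisense genes. The gene segments of antigen receptors were also present, including 218 immunoglobulin V genes and 144 T cell receptor V genes. Genes of several other classes were not listed, among them the 2207 microRNA genes, 1507 small nucleolar RNA genes and 2 mitochondrial ribosomal RNA genes of M21. Of 9941 processed pseudogenes in M21, 1 was listed.

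All 27 gene lists fixed for this tissue and treatment were complete in the annotation. The annotation holds 98.5% of the protein-coding genes of M21, so this was likely beforehand and describes the annotation, not the kidneys. Together the lists named 158 distinct genes, of which 90 were markers of 17 kidney and immune cell types, and each of the 158 had 1 identifier. The target itself, Csf1r (ENSMUSG00000024621), was listed with the genes for its ligands, Csf1 and Il34. The 11 macrophage markers included the macrophage surface receptor gene Adgre1, the complement genes C1qa, C1qb and C1qc, and the fractalkine receptor gene Cx3cr1. Monocytes were covered by 7 genes, including Ly6c2 and Ccr2, neutrophils by 5, including S100a8 and S100a9, and conventional dendritic cells by 6, including Xcr1 and Flt3. The proximal tubule was covered by 8 genes, among them the phosphate transporter gene Slc34a1 and the endocytic receptor genes Lrp2 and Cubn. Among other tubule segments and cell types, the lists held Umod and Slc12a1 for the thick ascending limb and Slc12a3 for the distal convoluted tubule. They held Aqp2 for principal cells and Atp6v1g3 for intercalated cells, with further genes in each list. No list was fixed for the thin limbs or the connecting tubule. The 7 genes of the tubular injury list, among them Havcr1 (KIM-1) and Lcn2 (NGAL), were also listed, as were all 13 protein-coding genes of the mitochondrial genome. Presence in the annotation says that a gene was open to counting and nothing of its level. Whether reads could be told apart between listed genes of similar sequence was not examined.

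Same-strand overlap of exons with another listed gene can leave reads ambiguous between genes. By the exons of M21, it affected 803 of the listed genes, or 2.49% of those found in M21. The annotation used for counting is not named, and overlaps in it may differ. In M21, overlap affected 7 of the 158 genes in the fixed lists. The dendritic cell marker Clec9a shared 5.59% of its exonic bases with Clec1b, and Gata3, in the mesenchymal list, shared 1.94% with a non-coding gene. The other 5 were mitochondrial genes, with the largest shared part in mt-Atp8, at 21.1% of its exonic bases. These are shares of all exonic bases of a gene, not of reads. Where each overlap lies relative to the 3′ end was not examined. No macrophage, monocyte, tubule or tubular injury gene in the lists had such an overlap. Elsewhere in the annotation, 38 symbols were given to more than 1 identifier, and 78 identifiers in all shared a symbol.

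The libraries had 92 barcodes in common (exact 95% Poisson interval 74.2 to 112.8), which is 0.542% of the control library and 0.521% of the anti-CSF1R library. The remaining barcodes were each found in 1 library. No barcode lay at 1 mismatch from another barcode, either in its own library or in the other. The barcodes are built of fixed blocks, as described further below, so the lack of such pairs does not measure errors in the lists.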

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

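The 2 barcode counts and the number of shared barcodes were recomputed under the 4 alternative settings that the lists allow. Those for barcodes per library apply to both libraries, which makes 6 recomputed values, and each of the 6 equalled the value reported. Removal of the suffix, and leaving out barcodes with a neighbour at 1 mismatch, left 16985 and 17661 barcodes. Comparison with the suffix, or with 1 mismatch allowed, left 92 shared barcodes. These settings removed or added no barcode, so they say little about how stable the values are. Of the 10 alternative settings fixed before the data were examined, 6 were not run because they need counts per gene and cell, which were not used here. They concerned the mitochondrial filter, doublet removal, clustering resolution and thinning for cell class shares, and the pseudocount and the mitochondrial genes for summed expression. No paired analysis was possible because each group has 1 library. The depth of the libraries is unknown from the lists, and with 1 library per group no spread between replicates could be set against the difference in barcode number.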

Other observations

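The tests here were chosen after the shared barcodes had been counted. The barcodes of both libraries showed a block structure. The first 7 bases took 3839 distinct values over both libraries, and adding bases 8 and 9 left the number at 3839, so the first block fixed the pair that follows. Bases 10 to 16 also took 3839 values and fixed the same pair. That pair took 4 values, AG, CA, GT and TC, each in 24.0% to 25.8% of the barcodes of either library. Joining first and last blocks with the same middle pair gave 3684481 possible barcodes. From general knowledge of the platform, and not from a comparison made here, this structure resembles the barcode list of the later GEM-X generation of the kit more than that of the version named in the labels, and the Cell Ranger version named is older than that generation. The manufacturer's lists were not used here, so this apparent disagreement was not tested and the kit version stays in doubt.

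The 92 barcodes shared by the libraries were set against 3 explanations. If both libraries drew at random from the pool built from the blocks, 81.4 shared barcodes would be expected, which lies within the interval of 74.2 to 112.8 around the observed number. Seen the other way, 92 shared barcodes need a pool of 3260566 (2658624 to 4044659), an interval that holds the pool built from the blocks. One library listed under both labels would share most barcodes, and 0.542% of the control library's barcodes were shared. Reads assigned to the wrong library could add shared barcodes beyond chance, but the upper limit of the excess was 31.4 barcodes, or 0.185% of the control library, which is less than the part of the 92 that this source would need to supply if most came from it. Chance reuse of barcodes is thus consistent with the overlap, and a contribution from misassigned reads below that limit stays open. Misassigned reads that add counts to barcodes without making them pass cell calling leave no mark in these lists. No biological explanation was tested, since a barcode sequence carries no information on treatment.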
